A study of Mus musculus with 6 samples.

How the data were processed

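Genomic DNA from mouse liver was digested with HpaII and, separately, with MspI, and the products of ligation-mediated PCR were labelled with Cy5 (HpaII) and Cy3 (MspI), per the labels. Each of 6 samples, 3 exposed to a control diet and 3 to a high fat diet in utero, was hybridised to 1 array with both products and no dye exchange, so a dye effect is shared by all arrays and cannot be removed from a ratio's level. The deposited scanner files hold 1 intensity per probe and channel on a linear scale, extracted with NimbleScan 2.4.67, per the file headers. Whether the authors corrected the background of these intensities is not given in the sources used here. Of the 12 images, 11 were extracted on 1 day and the MspI image of high fat array 1 on another, so this day could not be used as a block. The authors' value table holds a log2 ratio per fragment, whose base and direction were taken from its comparison with the scanner values. Its columns followed the log2 HpaII over MspI ratio with a slope of 0.983 to 1.005 and Pearson's r of 0.985 to 0.992 across fragments for 5 arrays. For high fat array 3 r was 0.961, and its scanner values correlated slightly better with another array's column. The median of the authors' columns was -1.93, -2.02 and -1.92 for the control and -2.25, -1.88 and -2.08 for the high fat arrays. The normalization behind that table is not given in the sources used here, and it served only as an alternative.

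Probes were grouped by the fragment their identifier names, 801222 fragments in all, of which 9 are mitochondrial. Coordinates are 1-based and as in the files. The assembly is not given in the sources used here. The last fragment of chromosome 1 ends at 197069962, which is the length of that chromosome in the older mouse assembly mm8. The gene table at hand belongs to a later assembly, so no coordinate was converted and no fragment was assigned to a gene. The planned comparisons of promoters, gene lists, cell type markers and the genes of interest, with their own alternatives, were therefore not made.

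The log2 HpaII over MspI ratio of each fragment was the 20% trimmed mean of its probes, which leaves out no probe for fragments of 1 to 4 probes. Signals were used as given, with no background subtraction and no loess or quantile step, and each array was centred on its median. A minimum of 5 probes had been planned, or the number per fragment if lower. As 498949 fragments carry 3 probes and few carry more than 4, the minimum was set at 3. A fragment was compared when its MspI signal exceeded the median plus 2.5 median absolute deviations of the 24079 random control probes on all 6 arrays. This left 435630 fragments. Where a fragment's HpaII signal was below the same limit on all 3 arrays of a group, the limit took its place and the change is given as at least that size, which stays open to dye bias. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) without a block, with Benjamini-Hochberg adjustment at 0.05. A call is a fragment under that threshold. The fragments named are the 10 per direction with the largest difference among the calls, a rule fixed before the data were examined. Shares and class differences per array were compared with exact two-sided permutation tests, whose smallest p is 0.1. Dense fragments were those with at least 7 fragment starts within 1 kb of the midpoint.

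The MspI signal was also compared on its own, after quantile normalization between arrays, over 550403 nuclear fragments with at least 3 probes and no filter on signal. The limma step was tested on simulated data with the spread of the real fragments. For the ratio it recovered 17% of 100 changes of 1 and 89% of 100 changes of 2 on the log2 scale, with 3 false calls among 435630 fragments. For the MspI signal it recovered 31% and 84%, with 3 false calls among 550403 fragments. The simulated noise was normal and independent between fragments and arrays, without effects shared by an array or a stretch of the genome. These false calls therefore do not measure the error behind the counts in the real data.

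Alternatives fixed before the data were examined were the replicate number as a block, no centring, centring on random control probes, and quantile normalization of the ratios. Further ones were a loess within arrays, quantile normalization of each channel within 20 bins of fragment length, normexp with an offset of 50, no detection filter, and a filter leaving out the lowest 25% by MspI signal. The median over probes, eBayes with trend and robust settings, the array-number lot as a block, the authors' value table and leaving out each array completed the list. Fewer probes per fragment, centring on mitochondrial DNA, and leaving out fragments or windows with an MspI difference were added after the data were seen, as was the MspI comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.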

Results

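DNA methylation was measured in liver of wild-type CD1 mice, an outbred stock, that had been exposed in utero to either a control diet or a high fat diet. The question set by the design is where the liver methylome of animals exposed to a maternal high fat diet differs from that of control animals. Each group held 3 samples with 1 array each. The HELP assay cuts genomic DNA with HpaII, which cuts CCGG only when the site is unmethylated, and in parallel with MspI, which cuts CCGG whether or not the inner cytosine is methylated. The fragments are amplified by ligation-mediated PCR, and the 2 products are hybridised together to a tiling array. HpaII products carried Cy5 and MspI products Cy3 on each of the 6 arrays, so a higher log2 HpaII over MspI ratio means less methylation where the MspI signal is alike. The labels do not say whether the samples of a group came from different litters, and p-values measure only the spread between these samples.

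The array held 801213 nuclear HpaII fragments of 50 to 2000 bp, and 435630 of them were compared. Signal over background, which takes the place of depth, varied between arrays. The median MspI signal was 3.89, 3.71 and 4.94 times that of the random control probes on control arrays 1, 2 and 3. It was 4.32, 5.76 and 2.37 times that level on high fat arrays 1, 2 and 3. On high fat array 3, 79.7% of nuclear fragments had an MspI signal above the random controls, against 88.2% to 91.1% on the other 5 arrays. The median HpaII signal was 5.39, 5.46 and 5.44 times the random controls on control arrays 1, 2 and 3. It was 4.39, 5.07 and 2.95 times on high fat arrays 1, 2 and 3, lower on each than on any control array. HpaII was above the random controls for 68.6% to 77.3% of nuclear fragments on control and 52.9% to 69.3% on high fat arrays. This lower HpaII signal runs along the diet contrast, and a technical origin cannot be told from methylation here. The number of arrays limits the precision of each value below.

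The ratio had the same overall form in both groups. Most fragments lay in a broad methylated peak below 0 and fewer in a hypomethylated peak above it. The share of fragments with a ratio above 0 was 19.8% ± 1.48 (SD, n = 3) in control liver and 17.7% ± 2.61 (SD, n = 3) in high fat liver. The difference of -2.11 percentage points was within the spread between arrays (exact two-sided permutation test, p = 0.2, where 0.1 is the smallest p that 3 against 3 can give). The lowest share, 15%, belonged to high fat array 3, and without that array the difference was -0.77 points. It was -9.39 with centring on the random control probes, -0.13 after loess and -0.25 with channel quantiles in length bins. Loess and channel quantiles bring the arrays to a like level or distribution, so they leave the share little room to differ. The difference was -0.02 with each array centred on its mitochondrial DNA, a centring added after the data were seen. The limit of 0 then lies at an uncentred ratio of 1.71 to 2.1, depending on the array, which few fragments exceed. A very small difference follows from that limit. Counted above -0.82, the midpoint between the 2 peaks, the shares were 29.8% ± 2.43 and 26.7% ± 2.85 (SD, n = 3 each). The median uncentred ratio was -1.89 ± 0.19 in control and -2.03 ± 0.16 in high fat liver (SD, n = 3 each).

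**Figure D1:**
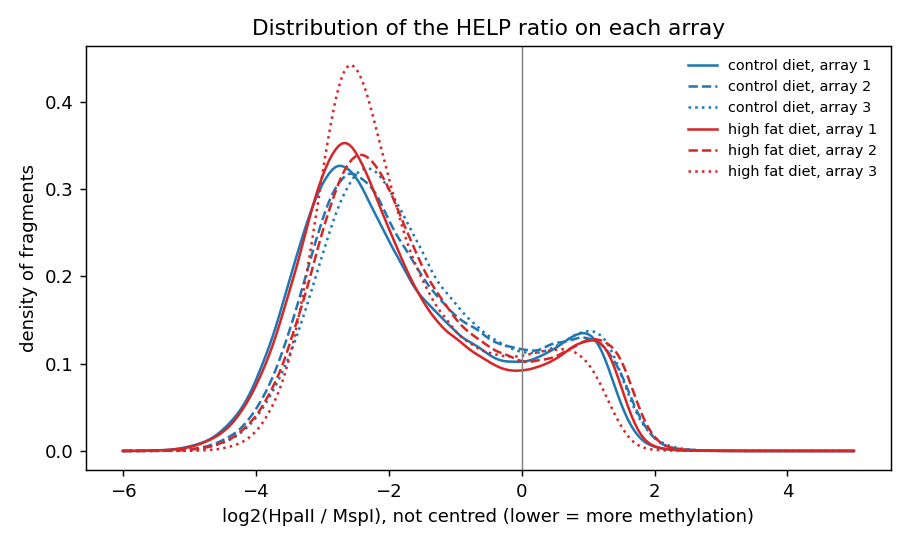
Density of the uncentred log2 HpaII over MspI ratio over the 435630 fragments compared, one line per array, control diet in blue and high fat diet in red. The 6 curves share a methylated peak below 0 and a hypomethylated peak above 0, and high fat array 3 has the narrowest distribution, with an SD of 1.32 against 1.48 to 1.54 on the other arrays.

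Single fragments differed strongly between the groups. After exposure to the high fat diet 411 fragments had a lower and 346 a higher ratio, 757 in all at an adjusted p under 0.05 in limma. For 360 of the 757 the MspI signal also differed at an unadjusted p under 0.05, and for 106 at an adjusted p under 0.05, so a ratio difference there is not a measure of methylation alone. The median difference was -1.03 among the lower and 1.01 among the higher fragments on the log2 scale. At chromosome 3, 96359073 to 96359669, with HpaII signal above the random controls on all arrays, the centred ratio was -0.60 ± 0.08 in control and 3.06 ± 0.44 in high fat liver (SD, n = 3 each). At chromosome 11, 32826476 to 32826763, also above the random controls on all arrays, it was 2.69 ± 0.34 in control and 0.22 ± 0.86 in high fat liver. Genes could not be assigned, since the files give positions alone and no annotation of their assembly was used here.

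Among the 10 fragments named for the largest measured rise of the ratio, 3 lay on chromosome 3. At chromosome 3, 96359073 to 96359669, the ratio was higher in high fat liver by 3.66 (SE 0.19, adjusted p = 2.3e-08), a 12.7-fold change, and by 2 or 4-fold after a loess on signal intensity within each array. At chromosome 3, 135782128 to 135783457, the HpaII signal of every control array was not above the random controls, so the change is a bound of at least 6.7-fold (adjusted p = 4.34e-07). At chromosome 3, 20390095 to 20390806, the difference was 2.34 (SE 0.15, adjusted p = 4.81e-07). Chromosome 4 held 3 more of these 10. The fragment from 118817772 to 118817962 was at least 8.4-fold higher in ratio (adjusted p = 1.36e-09), and that from 37079799 to 37080283 at least 3.2-fold higher. The fragment from 97764650 to 97765691 was higher by 2.54 (SE 0.16), with HpaII above the random controls on 1 of the 3 control arrays. On chromosome 2, the fragment from 104211658 to 104212227 was higher by 2.32 (SE 0.18), and that from 173732047 to 173732369 was at least 3.9-fold higher. The fragment at chromosome 18, 80265479 to 80266453, was at least 4.2-fold higher. The fragment at chromosome 7, 118598064 to 118598351, differed by 2.57 with an SE of 0.51 (adjusted p = 0.0466). Its control values were 2.37, -0.65 and -0.72, so control array 1 lay near the high fat arrays.

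Among the 10 fragments named for the largest measured fall, 4 lay on chromosome 17. The abutting fragments at chromosome 17, 83274820 to 83275816 and 83275817 to 83275951, share a cut site and were both lower in high fat liver. Their HpaII signal was not above the random controls on any high fat array, so they were at least 3.2-fold and at least 4.5-fold lower (adjusted p = 1.81e-06 and 4.67e-07). The fragment at chromosome 17, 84844996 to 84845248, was at least 3.5-fold lower, and that at chromosome 17, 31085178 to 31085433, fell by 2.18 (SE 0.17, adjusted p = 4.06e-06). At chromosome 6, 35793751 to 35794884, the ratio was 2.68 ± 0.11 in control and 0.32 ± 0.27 in high fat liver (SD, n = 3 each). At chromosome 4, 140632441 to 140632746, it was 2.06 ± 0.13 and -0.20 ± 0.16. In 3 further fragments 1 high fat array lay apart from the others. High fat array 3, the one with the high background, was at 1.19 against -0.09 and -0.44 at chromosome 11, 32826476 to 32826763. It was at 0.55 against -0.87 and -0.71 at chromosome 14, 33185098 to 33185849, where HpaII was above the random controls on 1 high fat array. High fat array 1 was at -0.05 against -2.13 and -1.7 at chromosome 18, 80442805 to 80443147. With trend and robust eBayes these 3 were not called (adjusted p = 0.243, 0.209 and 0.335 in limma). The ratio of the fragment at chromosome 1, 185939705 to 185940763, fell by 2.23 (SE 0.16, adjusted p = 1.81e-06), while its MspI signal rose by 2.52.

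For 4 of these 20 fragments the MspI signal, the denominator of the ratio, also differed between the groups at an adjusted p under 0.05 in limma. At chromosome 1, 185939705 to 185940763, the MspI signal was higher in high fat liver by 2.52 on the log2 scale. That is no less than the fall of 2.23 in the ratio. The fall of this fragment can thus come from the denominator alone and is not read as more methylation. The sign of this fragment's difference was turned in the authors' value table, at 0.23 (adjusted p = 0.674). At chromosome 4, 118817772 to 118817962, at chromosome 2, 173732047 to 173732369, and at chromosome 4, 37079799 to 37080283, the MspI signal was higher by 1.52, 1.39 and 1.11, in the direction of the ratio. The other 16 differed in the ratio with an MspI difference between -0.52 and 0.29 and no MspI call, though 6 of them had an unadjusted MspI p under 0.05. These 6 were chromosome 3, 96359073 to 96359669 (MspI difference -0.52), chromosome 3, 135782128 to 135783457 (-0.31), chromosome 2, 104211658 to 104212227 (-0.38), chromosome 14 (-0.38), and chromosome 17, 83274820 to 83275816 (0.29) and 84844996 to 84845248 (-0.51). In 4 of the 6 the MspI difference adds to the size of the ratio difference. Of the 20 fragments, 16 lay in a 1 Mb window that holds an MspI call.

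A loess of the ratio on signal intensity within each array ended the call of 11 of the 20 fragments and left 9 called. Intensity here is the mean log2 signal of HpaII and MspI. A change in HpaII signal alone thus moves a fragment along the fitted curve, and the step can take away part of a real change. A call lost with loess therefore does not tell a real difference from an effect of intensity. At chromosome 4, 118817772 to 118817962, the difference was 0.68 after loess (adjusted p = 0.634 in limma). At chromosome 2, 173732047 to 173732369, it was 0.40, and at chromosome 4, 37079799 to 37080283, it was 0.81. Among the higher fragments, those at chromosome 3, 20390095 to 20390806, and at chromosome 7 also lost their call, at 1.1 and 0.83. Among the lower ones, the differences after loess were -0.74 on chromosome 11, -1.04 on chromosome 14, -0.82 on chromosome 6 and -1.02 on chromosome 18. They were -0.73 at chromosome 4, 140632441 to 140632746, and -0.97 at chromosome 17, 84844996 to 84845248. Most of the 9 kept changed in size as well. Among the higher ones the difference became 2 at chromosome 3, 96359073 to 96359669, 2.2 at chromosome 3, 135782128 to 135783457, 2.04 on chromosome 18, 1.61 at chromosome 4, 97764650 to 97765691, and 1.32 at chromosome 2, 104211658 to 104212227. Among the lower ones it became -2.27 and -1.64 at the abutting fragments of chromosome 17, -1.56 at chromosome 17, 31085178 to 31085433, and -3.52 on chromosome 1. The fragment of chromosome 1 is the one whose MspI signal rose by 2.52. Of the 8 fragments given above with a bound, 7 had a difference after loess that was smaller than the bound. So these bounds hold only without that step, and only that of chromosome 17, 83274820 to 83275816, was kept with it.

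**Figure D2:**
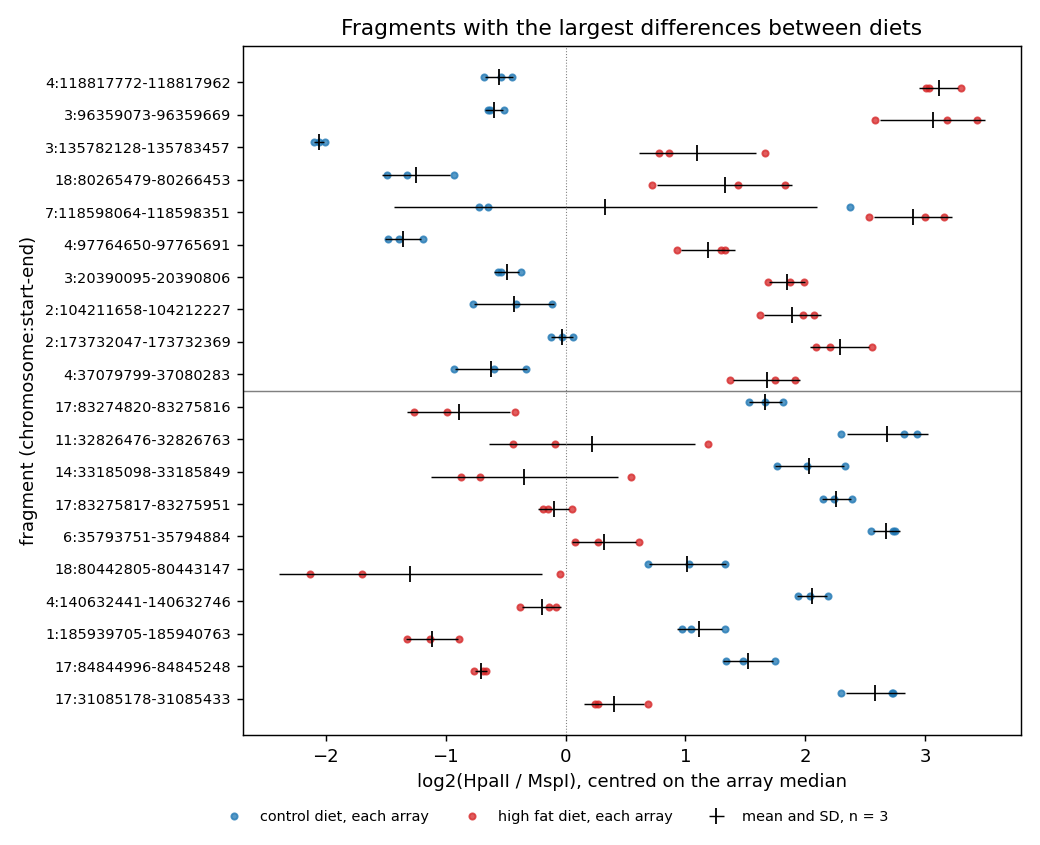
Centred log2 HpaII over MspI ratio of the 20 fragments with the largest differences, 10 per direction, with a point per array and the mean and SD (n = 3) of each diet group. The upper 10 are higher and the lower 10 lower in high fat liver, and only the fragment of chromosome 7 has a control array, at 2.37, close to the high fat values of 2.53 to 3.16.

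The balance of directions depended on the centring of the arrays. Lower fragments made up 54.3% of the calls after centring on the array median, 76.1% of 2132 calls without centring and 95.1% of 2545 calls after centring on the random control probes. The median difference over all fragments was 0.05, -0.08 and -0.31 under these centrings, and differences here are relative to the array median. The number of calls also rested on single arrays. It was 435 without control array 1, 252 without control array 3 and 1264 without high fat array 3. By the numbers of the arrays, 3 lots were formed. With lot as a block there were 1136 calls. In the lot of 1 control and 1 high fat array, and in the lot of 2 control and 1 high fat arrays, each of the 757 calls had the direction of the full comparison, as the selection on the same arrays favours.

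Part of the calls were gathered in few stretches of the genome. Of 2594 windows of 1 Mb, 29 held at least 5 calls and together 249 of the 757, or 32.9% of the calls on 2.4% of the fragments. The other 508 calls were spread more thinly, 213 of them alone in their window, and 354 windows held a call. The fullest window, chromosome 4 from 140 to 141 Mb, held 36 calls among 773 fragments, 24 lower and 12 higher in high fat liver. Chromosome 18 from 80 to 81 Mb held 21 calls, 10 lower and 11 higher. On chromosome 10 the adjoining windows from 83 to 86 Mb held 11, 12 and 7 calls. Chromosome 2 from 143 to 144 Mb held 12. Calls of both directions lay side by side in 27 of the 29 windows. The exceptions were chromosome 19 from 44 to 45 Mb, where all 9 calls were lower, and chromosome 5 from 125 to 126 Mb, where all 5 were lower. These counts moved with single arrays, as did the whole count of 757, which was 252 without control array 3 and 435 without control array 1. On chromosome 4 from 140 Mb, chromosome 18 from 80 Mb, chromosome 10 from 84 Mb, chromosome 2 from 143 Mb and chromosome 10 from 83 Mb, 18, 6, 5, 4 and 1 calls were made without control array 3, and 20, 11, 6, 7 and 2 without control array 1. Of these, only the count on chromosome 10 from 83 Mb fell much further than the whole count. It was also 5, 7 and 23 without high fat arrays 1, 2 and 3. In 10000 random deals of 757 calls to the fragments, no window held more than 10 calls. In 24 of the 29 windows at least 1 fragment also differed in MspI signal. The 277 windows of 1 Mb with an MspI call held 14.1% of the fragments and 511 of the 757 calls (67.5%), and 246 calls lay outside them. Fitted and adjusted anew without these windows, the comparison gave 52 calls. Of the 757 calls, 397 had no MspI difference at an unadjusted p under 0.05, and the comparison fitted anew without fragments with such a difference gave 274. Windows and the minimum of 5 calls were chosen after the data were seen.

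**Figure D3:**
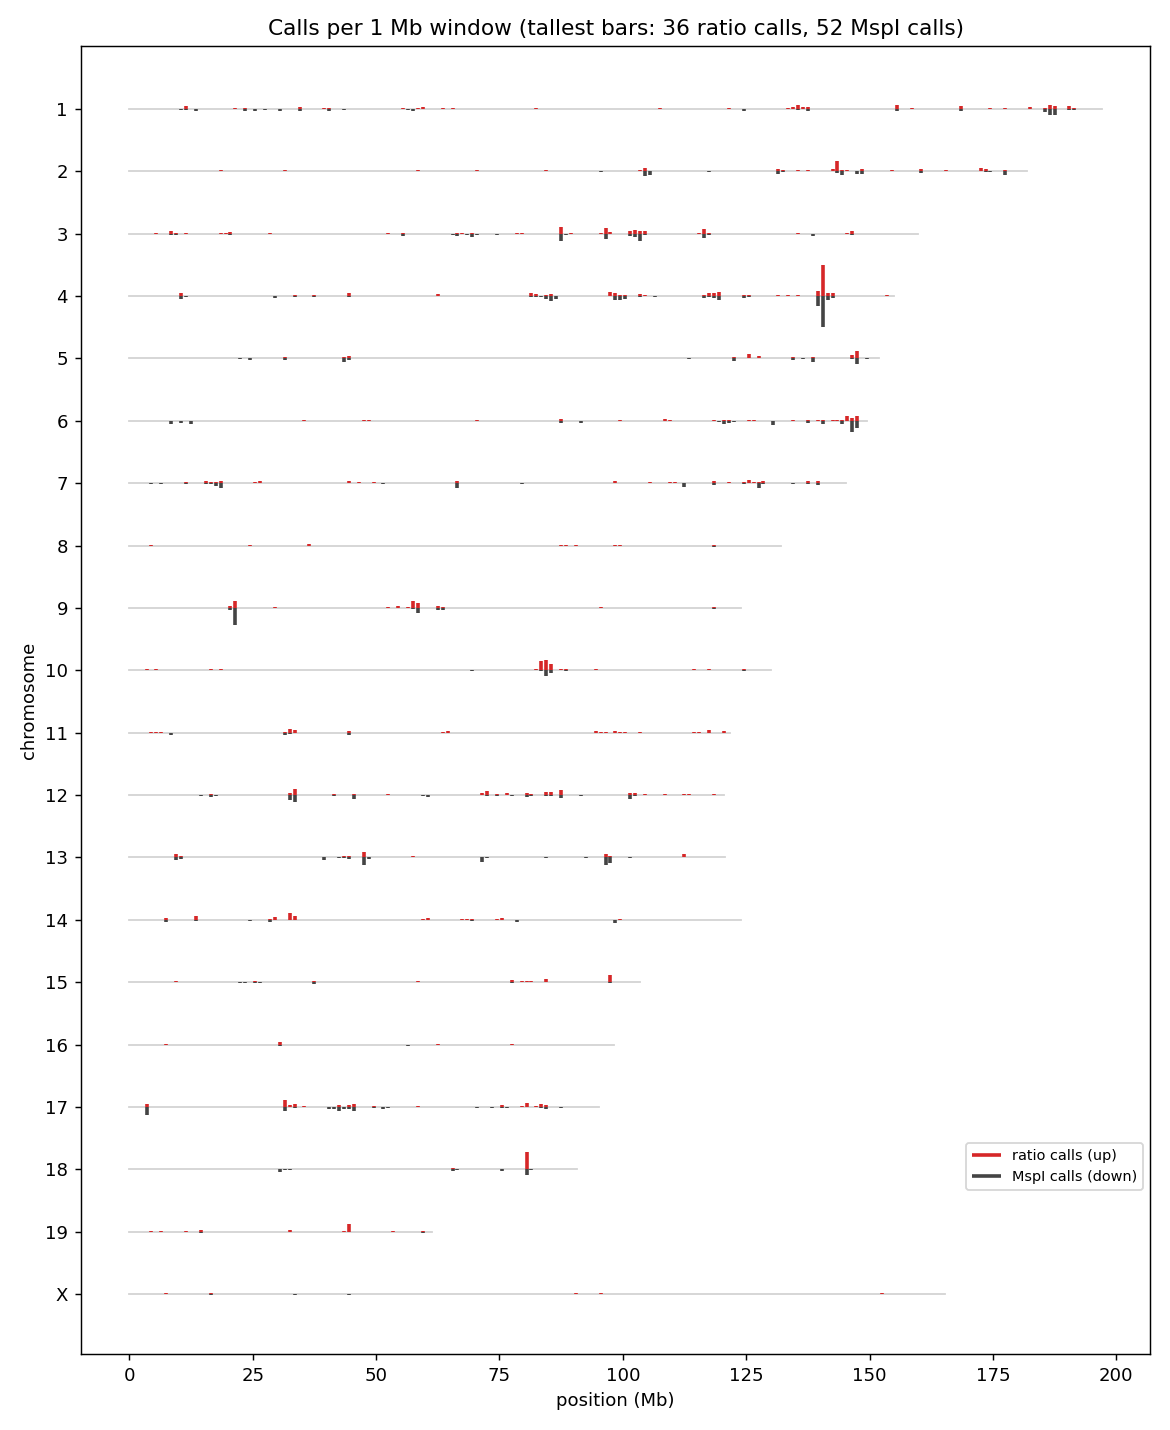
Number of called fragments per 1 Mb window along chromosomes 1 to 19 and X, with ratio calls as bars upward and MspI calls as bars downward from each chromosome's line, each kind scaled to its own tallest bar. The tallest bars, 36 ratio calls and 52 MspI calls, stand in the same window of chromosome 4 from 140 to 141 Mb.

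**Figure D4:**
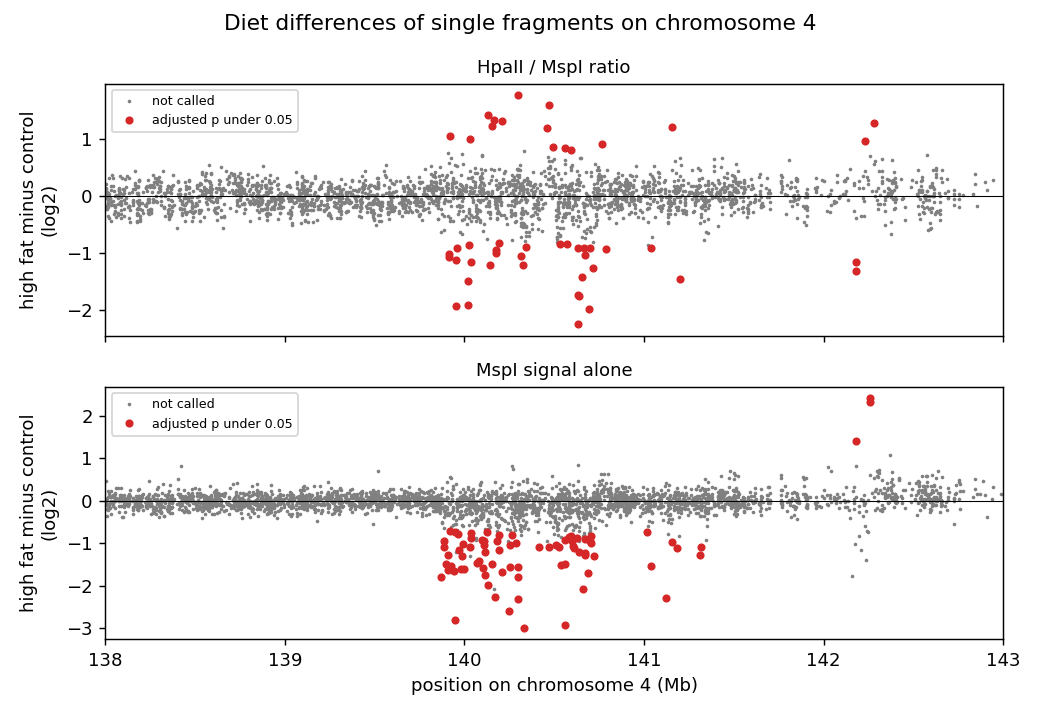
High fat minus control difference (log2) of single fragments on chromosome 4 from 138 to 143 Mb, for the ratio above and the MspI signal below, with called fragments in red. Ratio calls of both directions and MspI calls that are all lower lie together between 139.87 and 140.72 Mb.

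Among the autosomes and chromosome X, the rate of calls was 32.3 per 10000 fragments compared on chromosome 4 (99 calls), 31.6 on chromosome 3 (61 calls) and 28.2 on chromosome 12 (51 calls). Outside the window from 140 to 141 Mb, chromosome 4 had 63 calls, or 21.1 per 10000. The rate was 3.9 on chromosome 8 (10 calls), 4.3 on chromosome 16 (6 calls) and 5.8 on chromosome X (5 calls, all higher). These rates were not tested against each other.

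Without the adjustment, 742 fragments had an unadjusted p under 0.05 and a difference of at least 1 on the log2 scale, 381 lower and 361 higher in high fat liver. This balance too depended on the centring, with 659 lower and 222 higher without centring, and 1898 lower and 108 higher after centring on the random control probes. Without the minimum difference 51635 fragments passed, where 21782 would do so by chance alone. That count was 29129 with centring on mitochondrial DNA, 30364 with loess, 35180 without centring and 80873 with centring on the random control probes. Leaving out high fat array 3 raised the count of 742 to 1213.

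Regions dense in HpaII sites, which stand in for CpG-dense regions, carried few of the differences. Fragments with at least 7 fragment starts within 1 kb of their midpoint were largely hypomethylated, with 90.8% above the midpoint between the peaks, against 23.8% of other fragments. Of these 27472 dense fragments 15 were called, 4 lower and 11 higher, against 742 calls among 408158 others. The odds ratio was 0.3 (95% confidence interval 0.17 to 0.5, Fisher's exact test, two-sided, p = 3.19e-08, over fragments, which are not independent). This does not tell density from ratio level, since the median ratio of dense fragments was 0.75. Among all fragments more than 2 above the array median, calls were also few, 35 lower and 18 higher among 79578. Among those 0.5 to 2 above it, 219 were lower and 67 higher among 87013. No shift of dense fragments as a class was detected. The median ratio of dense minus other fragments was 2.76 ± 0.13 in control and 2.85 ± 0.19 in high fat liver (SD, n = 3 each, exact two-sided permutation p = 0.7). This difference of 0.09 was turned to -0.085 by a loess within each array. It was 0.001 without high fat array 1, 0.187 without high fat array 3, 0.162 without control array 1 and 0.04 without control array 3. The density limit was set on the ratio's level after the data were seen.

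The median ratio of chromosome X minus that of the autosomes was -0.34, -0.41 and -0.31 on the control arrays and -0.24, -0.26 and -0.24 on the high fat arrays. The group means were -0.35 ± 0.05 and -0.25 ± 0.01 (SD, n = 3 each). The difference of 0.107 had all high fat arrays above all control arrays, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give, so it does not pass 0.05. The difference was 0.004 after loess within each array (exact permutation p = 0.9), 0.038 with channel quantiles in length bins and 0.057 with quantile-normalized ratios.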

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

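The comparison of the MspI signal on its own, and the tests on splits, on sequence differences and on uneven spacing of fragments, were chosen after the results were seen. The tests of a shared cut site, of background and of copy number had their outcome unseen when they were set.

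A signal outside the planned comparisons came from the MspI channel. MspI cuts whether or not the inner cytosine is methylated. In limma, 964 fragments differed in MspI signal between the diet groups at an adjusted p under 0.05, 445 lower and 519 higher in high fat liver. This balance depended on the scaling, with 135 lower and 270 higher after median centring, and 414 against 663 without control array 2. Of the 964 fragments, 401 passed the signal filter for the ratio. The highest of the other 9 splits of the 6 arrays gave 128, so 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the diet split did not stand out. It gave 33426 fragments, below the 34087, 35247 and 38901 of splits that mixed the diets. Many of the calls lay in runs. In 38 of the 60 windows of 1 Mb with at least 5 MspI calls all calls had one direction, and in 22 both directions occurred. With no gap over 200 kb, the run with the most calls lay on chromosome 4 from 139868182 to 140720728, where all 69 MspI calls were lower in high fat liver, beside 28 lower and 12 higher ratio calls. The next runs were on chromosome 6 from 146466442 to 147377655, with 31 calls, all lower, and on chromosome 13 from 96741398 to 97094683, with 22, all lower. On chromosome 1 from 186721223 to 187218533 all 19 were higher, as were all 18 on chromosome 9 from 20975276 to 21600315.

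The high background of high fat array 3 is argued against as the whole cause, since the count rose to 3248 without that array (and fell to 640 without control array 3). A copy number difference over most of a 1 Mb window would move most of its fragments. In the 60 windows of 1 Mb with at least 5 MspI calls the median difference of all fragments was 1.7% of that of the called ones. The exception was chromosome 2 from 177 to 178 Mb, where it was 0.69 against 1.34 over 27 fragments. A shorter copy number difference can leave such a median unmoved. The runs named above span 0.35 to 0.91 Mb, so shorter differences stay open. A cut site lost or gained in one group should change the neighbours on both sides. Neighbours that share a site were called together in one direction at 2.04 times the odds of neighbours that share none (95% confidence interval 1.03 to 4.4, Fisher's exact test), between the limits set for and against it, which leaves it open.

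The gathering of part of the ratio calls, 249 of 757, in 29 windows was the next pattern. Uneven spacing of fragments does not give it, since the fullest window held 36 calls and 10000 random deals at most 10. The probes of the calls were spread over rows at 99.4% of the standard deviation of all probes. For the 112 probes of calls in the fullest window it was 100.7% over rows and 104.5% over columns. A single blemish behind all calls or behind the fullest window is argued against. Several small blemishes, or one behind another window, would leave these values unmoved. For 397 ratio calls no difference of their own MspI signal was detected (unadjusted p of 0.05 or more in limma). Of these, 39.8% lay within 100 kb of another fragment with an MspI call. In 10000 circular shifts along the genome the median was 4.8% and the highest 35%. A smaller MspI shift can remain in such calls and enters their ratio, so part of their nearness to stretches with MspI calls may be built in. A candidate explanation is that the groups carried different haplotypes in these stretches, which may come from related or littermate animals of an outbred stock, so that sequence changes at cut sites or under probes, or methylation that follows sequence, add to any effect of diet. The labels give no litters and no genotypes were compared here, so whether ancestry differed between the groups is not known, and an effect of diet stays open for each fragment.

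For the ratio itself, 757 fragments were called for the diet groups and at most 41 in the other 9 splits, so 1 of the 10 splits reached the real count. For the fragments at unadjusted p with a difference of at least 1, the counts were 742 and at most 415, again 1 of 10. With 10 splits no share under 0.05 can be reached.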

How the results depend on the processing

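The replicate block and the settings of the preceding methods were fixed before the data were examined, and those on MspI differences, probe number and mitochondrial centring were added afterwards. The 757 calls became 2132 without centring, 2545 on random control centring, 427 with quantile-normalized ratios, 210 with loess, 440 with channel quantiles in length bins, 152 with the median over probes, 1529 with trend and robust eBayes, 1136 with the array-number lot as a block and 298 in the authors' value table. The 9 other alternatives for this count stayed within 1.5 times of it. The fragments called changed more than the counts. Of the 757, 108 were called in the same direction with loess, 134 with the median over probes and 151 in the authors' table. The most shared with any alternative was 653, with trend and robust eBayes. Among the 9 alternatives with a like count, 406 (without high fat array 1) to 599 (at least 2 probes) were shared. Leaving out 1 array gave 252 (without control array 3) to 1264 (without high fat array 3), with 435 without control array 1. Leaving out fragments with an MspI difference gave 274 calls, and leaving out the 277 windows with an MspI call gave 52. Those windows held 14.1% of the fragments and 511 of the 757 calls, so 246 calls lay outside them in the full comparison. Same-numbered arrays deviated together at most weakly (r of 0.092, -0.029 and 0.021, against -0.074 to 0.05 for arrays of unlike number). The value of the arrays numbered 1 was the highest, so a pairing by number is not fully excluded. The replicate block gave 379 ratio and 616 MspI calls.

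The 742 fragments at unadjusted p became 2006 on random control centring, 1154 with loess, 1407 with no detection filter, 1352 with the median over probes, 484 with trend and robust eBayes, 1512 in the authors' table, 1149 with 1 probe or more, 386 and 329 without fragments or windows of MspI differences, and 51635 without a minimum difference. Leaving out 1 array gave 762 to 1213. The MspI count of 964 became 405 with median centring and ranged from 640 (without control array 3) to 3248 (without high fat array 3). The dense class difference turned to -0.085 with loess and ranged from 0.001 to 0.187 with 1 array left out. The fall at chromosome 1, 185939705 to 185940763, turned to 0.23 in the authors' table. The cause of these changes was not tested.

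The difference in the share of hypomethylated fragments ranged from -9.39 (random control centring) to -0.02 (mitochondrial centring), and that of chromosome X from 0.004 (loess) to 0.152 (authors' table). The smallest differences in the share came from mitochondrial centring, loess and channel quantiles, which leave it little room to differ. It still shrank to -0.77 without high fat array 3. The difference of chromosome X all but vanished with loess. The exact tests, which cannot pass 0.05 here, say nothing of the stability of either. Quantile-normalized ratios fix the share of hypomethylated fragments, so it gives no value there. Of the 20 named fragments 8 were called in every alternative that tested them, and loess, which can take away part of a real change, ended the call of 11. Of these 8, only chromosome 4, 97764650 to 97765691, was tested in all 24 alternatives, and the others in 21 to 23. The alternative without windows of an MspI call did not test 16 of the 20. The fragment of chromosome 7, 118598064 to 118598351, was called in 6 of 23. Promoter and gene list alternatives were not run. Signal over background limits high fat array 3 most, at 2.37 times the random controls for MspI and 2.95 times for HpaII. For HpaII it was lower on every high fat array than on any control array.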

Other observations

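The classes of fragments described here were set after the data were seen, and no explanation was tested for them.

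The run of chromosome 4 from 139868182 to 140720728 spans 0.85 Mb and shows how the channels differ. Of 807 fragments compared for MspI, 69 were called and all were lower in high fat liver. Of 649 compared for the ratio, 40 were called, 28 lower and 12 higher. In the 1 Mb from 140 Mb the median MspI difference was 0.08 in the direction of the calls over all 935 fragments and 1.11 over the 52 called ones. The fragment from 140632441 to 140632746 lies in this run and had an MspI difference of 0.02.

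Fragment length went with the direction of the calls and with the median difference of all fragments. That median was 0.123 for fragments up to 200 bp, 0.118 up to 400 bp, 0.02 up to 1000 bp and -0.025 above. Of the calls in fragments over 1000 bp, 74% were lower in high fat liver (165 of 223), against 48.6% of those over 400 and up to 1000 bp (140 of 288), 41.3% of those over 200 and up to 400 bp (59 of 143) and 45.6% of those up to 200 bp (47 of 103). By methylation level, calls below the array median were mostly higher and those above it mostly lower in high fat liver. Among fragments more than 1 below it, 10 calls were lower and 90 higher, and without high fat array 3 these were 23 and 90. HpaII was above the random controls for only 52.9% to 77.3% of nuclear fragments per array. Near that floor a further fall cannot be measured, so this imbalance is not read as a change of methylation. Among fragments more than 1 below the array median, the median difference was 0.191 and 18% were higher at an unadjusted p under 0.05. Without high fat array 3, the array with the narrowest range, these values were 0.078 and 8%. Among fragments 0.5 to 2 above the array median, 219 calls were lower and 67 higher, and without that array 293 and 169. Among fragments more than 2 above it, 35 calls were lower and 18 higher, and without that array 49 and 50. At an unadjusted p under 0.05, 5.1% of this class were lower and 2.2% higher, and without that array 2.2% and 8.5%.

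Mitochondrial DNA had a high ratio on all arrays, 1.91 ± 0.2 in control and 1.81 ± 0.03 in high fat liver (SD, n = 3 each, exact two-sided permutation p = 0.6). The median ratio of dense chromosome X minus dense autosomal fragments was -0.15 to -0.09 on control and -0.16 to -0.08 on high fat arrays. The median log2 MspI signal of chromosome Y minus autosomal fragments was -1.05 to -0.98 on control and -1.11 to -0.74 on high fat arrays (exact two-sided permutation p = 0.7).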
